A study of Mus musculus with 12 samples.

How the data were processed

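The series holds 12 arrays of RNA from primary mouse embryonic fibroblasts, 3 for each of 4 groups made of 2 genotypes and 2 treatments. Per the labels, the MEFs came from embryos at e14.5 (C57BL/6 x 129Sv F1), were used at passage 4, and received Cre adenovirus at a multiplicity of infection of 100 for 16 h in 3% oxygen. They then spent 48 h in 3% oxygen and 24 h in normoxia with 5% carbon dioxide before 3 h with 100 µM DP or ethanol, and 100 ng of RNA was used per array, per the labels. Replicates are separate MEF lines per the labels, wild-type lines 3, 4 and 5 and dKO lines 1, 5 and 6; equal numbers in the 2 genotypes do not mark a shared embryo. Sex of the embryos, hybridization dates and the scanner are not given in the sources used here.

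The deposited values were log2 probe set summaries made by the authors with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes by median polish. Array medians lay between 3.87 and 3.98 log2, and the 95th percentile of blank control probe sets between 3.28 and 3.53. A group mean at or under that level is described as near the blank controls, and its change as understated. The number of arrays limits the precision. Scanned intensity files were not used here.

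Of 45141 probe sets, 104 controls were set aside. Exactly 1 gene symbol was listed for 28898, of which 28689 were updated through the gene identifier and 209 kept as listed; 551 with several symbols and 15588 with none were left out. The probe set with the highest mean over all arrays stood for each of 17097 genes, 7180 of which had more than 1. Chromosomes were taken from the GRCm38.p6 gene table. No filter on dim genes was applied.

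Tests used limma 3.58.1 in R 4.3.3 with lmFit and eBayes, 1 mean per group over all 12 arrays and no block. The 5 contrasts were DP against ethanol in each genotype, dKO against wild type in each treatment, and the difference between the DP effects (dKO minus wild type). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Standard errors are moderated by limma. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

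Tests, alternatives, 29 gene lists of 503 genes (448 measured) and the rule for named genes were chosen before the data were examined. Lists covered HIF targets of glycolysis and glucose uptake, other HIF targets, HIF pathway components, acetyltransferases and coactivators, iron, zinc, NRF2, p53, ATF4, unfolded-protein, immediate early, CREB, interferon and NF-kB responses, S phase, mitosis, matrix, smooth muscle, lipid synthesis, senescence, sex-linked genes and markers of 8 other cell types. Some genes stand on more than 1 list, such as Fos and Nr4a3. The 27 lists with at least 5 measured members were tested against all other genes with camera at its preset correlation of 0.01, adjusted over the lists of a contrast. Members were also counted with p adjusted over the list alone. The named genes were the 8 largest rises and 8 largest falls among called genes with 1 direction in all 3 lines, or without overlap of the groups for genotype and difference, up to 4 called members per list or 2 members of largest change where none passed, and a fixed set including Crebbp, Hif1a, Vegfa and Tfrc. Under DP only the fixed genes were named for the genotype comparison. The text leaves out some genes the rule selects; under DP the genes of other lists are given as counts.

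The share of the wild-type response kept in dKO was computed on genes called, with a log2 change of at least 1, from 2 wild-type lines and measured in the line held out and in the dKO lines. Mean list responses per line were compared with a 2-sided exact permutation test over the 6 lines.

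The pairing comes from the labels, where the same numbered MEF of a genotype was given both treatments. As a check, deviations from the group means of DP and ethanol arrays of a line correlated at 0.04, 0.32 and 0.36 in dKO lines 1, 5 and 6 and at 0.42, 0.06 and 0.33 in wild-type lines 3, 4 and 5, over genes with a mean of at least 5 log2. Of the 6 ethanol arrays, 4 correlated best with the DP array of their own line.

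Alternatives were the MEF line as a block (fixed for DP effects and their difference, random for genotype), an intensity trend, robust eBayes, array weights, cyclic loess, median centring, leaving out the dimmest 40% of genes, the mean of all probe sets or every probe set, only the arrays compared, a fold minimum of 1.5, and leaving out each array. For lists an estimated correlation was tried, and fry, which tests a list against no change rather than against the other genes, and for the share a log2 change of at least log2(1.5) and the 100 genes of largest change. After the data were seen, fits without the 2 deviating ethanol arrays (for lists with the preset and an estimated correlation), without their lines, and without X-linked and Y-linked genes were added. The array weight fit stopped before convergence, with weights from 0.24 to 4.93.

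The tests were tested on simulated data with 200 changed genes per contrast. Of 2-fold changes 89% to 95% were recovered in the 4 contrasts between groups and 69% in the difference of DP effects; of 1.5-fold changes 51% to 61% and 26% were recovered. Between 4.38% and 10.3% of the calls were false, a simulated share of 50% was recovered as 49.8%, and no list without a simulated shift was called. Each test was run on a single simulated data set. The simulated noise was independent between genes and no simulated array deviated. Each gene in the simulated share kept the same part of its response. That run therefore does not show how choosing genes by their wild-type rise affects the share when genes differ. In the data the estimated correlation was 0.36 for the glycolysis list and 0.55 for the smooth muscle list. The simulation therefore does not show how often camera calls such lists falsely.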

Results

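Gene expression was measured on microarrays in primary mouse embryonic fibroblasts (MEFs) taken from embryos at stage e14.5. Wild-type MEFs were compared with MEFs carrying conditional alleles of the genes for CBP and p300, paralogous lysine acetyltransferases that serve as coactivators of many transcription factors. Cells of both genotypes received Cre-expressing adenovirus, which makes the conditional cells CBP/p300 double knockout (dKO). Cultures of 3 wild-type and 3 dKO lines were treated for 3 h with 100 µM 2,2'-dipyridyl (DP) or with ethanol, the vehicle. DP chelates iron, inhibits the iron-dependent hydroxylases that mark hypoxia-inducible factor (HIF) for destruction, and is used to mimic low oxygen. Each line gave 1 array per treatment, so that the 12 arrays formed 4 groups of 3. Median log2 values of the arrays lay between 3.87 and 3.98, and the number of arrays limits the precision. Changes are differences of log2 values on 17097 genes, the value after ± is the SE of the change with n = 3 arrays per group, and adjusted p-values are from limma.

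Crebbp, which encodes CBP, was lower in dKO than in wild-type cells in ethanol, at -0.85 ± 0.16 (adjusted p = 0.000992). Under DP its difference was -0.76 ± 0.16 (adjusted p = 0.0022). Where its probe set lies relative to the deleted part is not given in the sources used here, so the value does not check the deletion, and Ep300 was not analysed here. Xist, the RNA that coats the inactive X chromosome of female cells, lay between 10.3 and 10.7 log2 on the 6 wild-type arrays and between 3.94 and 5.32 on the 6 dKO arrays. Eif2s3y, a Y-linked translation factor gene, lay between 2.49 and 3.29 on wild-type and between 7.08 and 8.93 on dKO arrays. Of the 4 measured sex-linked genes, 3 Y-linked genes were higher and Xist was lower in dKO in both treatments, and none passed the test for either DP effect. The difference between 3' and 5' probe sets of beta-actin, which grows as RNA degrades, lay between 0.23 and 0.25 log2 in wild-type ethanol, 0.28 and 0.38 in wild-type DP, 0.40 and 0.45 in dKO ethanol and 0.48 and 0.60 in dKO DP arrays. That of GAPDH lay between -0.03 and 0.15, 0.04 and 0.17, 0.19 and 0.21, and 0.10 and 0.19 in the same order of groups. The GAPDH difference separated the genotypes in ethanol but overlapped between them under DP. The ethanol arrays of wild-type line 5 and dKO line 1 stood apart from their groups, with mean correlations of 0.989 and 0.986 to the others, and their deviations from the group mean correlated with each other across genes (r = 0.844 over 8917 genes, which are not independent replicates).

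The first comparison asked which genes respond to DP in wild-type MEFs. Ankrd37, a HIF target encoding an ankyrin-repeat protein, rose by 4.86 ± 0.11 (adjusted p = 1.24e-10). Pgf, encoding placental growth factor, rose by 4.25 ± 0.21, Apln, encoding the vascular peptide apelin, by 3.73 ± 0.19, and Vegfa, encoding the main angiogenic growth factor, by 2.03 ± 0.12. Ppp1r3c, a glycogen-targeting phosphatase subunit gene, rose by 4.65 ± 0.20, and Smtnl2 rose by 4.22 ± 0.12 from a level near that of the blank controls, so that its fold is understated. Selenbp1 and Selenbp2, which encode selenium-binding proteins, rose by 5.10 ± 0.16 and 5.18 ± 0.18. These paralogs are nearly identical in sequence, and how far their probe sets share signal was not tested. In all, 808 genes changed, of which 522 rose and 286 fell, and among those changed at least 2-fold 220 rose and 17 fell. The count was 538 without the wild-type DP array of line 4.

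Targets of HIF rose as a group in wild-type cells. Of 20 measured genes of glycolysis and glucose uptake, 12 rose and none fell, or 16 adjusted over the list alone, with a median change of 1.1 (camera adjusted p = 5.58e-31, and 0.0236 with an estimated correlation). Among them the glucose transporter genes Slc2a3 and Slc2a1 rose by 3.49 ± 0.19 and 1.99 ± 0.15, and Pfkfb3, whose product makes the activator of phosphofructokinase, by 2.95 ± 0.13. Gbe1, the glycogen branching enzyme gene, rose by 2.25 ± 0.13 and the hexokinase gene Hk2 by 2.01 ± 0.09. Pgk1 and Ldha, 2 abundant glycolytic enzyme genes, did not pass, with changes of 0.32 ± 0.10 and 0.24 ± 0.09; Pgk1 passed without the 2 deviating ethanol arrays (adjusted p = 0.0158). Of 41 other HIF targets, 33 rose and none fell, or 36 adjusted over the list alone, with a median of 1.36 (camera adjusted p = 1.52e-69, and 3.67e-05 with an estimated correlation). Car12, a carbonic anhydrase gene, rose by 3.65 ± 0.15, the lipid droplet gene Hilpda by 3.42 ± 0.18, Egln3, which encodes a HIF prolyl hydroxylase, by 3.41 ± 0.13, and Adm, which encodes the vasodilator adrenomedullin, by 2.0 ± 0.12. The mitophagy receptor gene Bnip3 rose by 1.53 ± 0.11 and the carbonic anhydrase gene Car9 by 1.14 ± 0.22. Among 12 components of the HIF pathway itself, only Vhl passed, also adjusted over the list alone. This gene for the ubiquitin ligase subunit that recognises HIF rose by 1.78 ± 0.11, while Hif1a, Epas1 and Arnt, which encode HIF subunits, changed by 0.20 ± 0.17, 0.20 ± 0.17 and 0.03 ± 0.09.

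Genes of early signalling responses also moved in wild-type cells. Among 26 immediate early genes, 10 rose and 4 fell, or 10 and 8 adjusted over the list alone. Fosl1 and Fos, which encode AP-1 subunits, rose by 2.06 ± 0.19 and 1.97 ± 0.20, the stress gene Ier3 by 1.88 ± 0.10, and the orphan nuclear receptor gene Nr4a3 by 1.51 ± 0.11. The median of this list was -0.04 and its mean 0.33, and camera's call (adjusted p = 0.0348, upward) was lost with an estimated correlation (adjusted p = 0.639 with an estimated correlation), without the wild-type DP array of line 3 and without the 2 deviating arrays (adjusted p = 0.163). Of 17 targets of CREB, a factor that binds CBP, 5 rose and 1 fell, or 7 and 1 adjusted over the list alone, with a median of 0.26 (camera adjusted p = 5.18e-05, and 0.0405 with an estimated correlation). With an estimated correlation and without the 2 deviating arrays, camera no longer called it (adjusted p = 0.318). Besides Fos and Nr4a3, the CREB targets that rose included Sik1, a kinase gene of the CREB feedback loop, up by 1.77 ± 0.13, and the MAP kinase phosphatase gene Dusp4, up by 1.01 ± 0.17. Of 22 NF-kB and inflammatory genes, 6 fell and 2 rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.644; median 0.05, mean -0.18). The chemokine genes Ccl7, Ccl2 and Cxcl1 fell by 1.89 ± 0.19, 1.28 ± 0.17 and 1.46 ± 0.23, and the cytokine gene Il6 fell by 1.97 ± 0.27. Lif, encoding a cytokine of the same family, rose by 1.91 ± 0.10 and Tnfaip3, an inhibitor of NF-kB signalling, by 1.78 ± 0.10. Other falls were those of Dmrt2 (-2.02 ± 0.25), the dioxin receptor gene Ahr (-1.62 ± 0.21), the Notch ligand gene Jag1 (-1.41 ± 0.26) and Snai2, which encodes a repressor of epithelial genes (-1.33 ± 0.18).

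The remaining lists had few called members and no camera call in wild-type cells. Of 13 iron-handling genes only Slc40a1, the iron exporter gene, passed (-0.81 ± 0.18, adjusted p = 0.0211, and 0.0507 with the MEF line as a block), against 3 rises and 1 fall adjusted over the list alone. The transferrin receptor gene Tfrc changed by 0.93 ± 0.28 (adjusted p = 0.0983, and 0.0438 with the block), and by 0.55 without the 2 deviating arrays (adjusted p = 0.00975). Mt1, a metallothionein gene, was the only one of 6 zinc-response genes to rise (1.27 ± 0.10), and Gclc, the glutathione synthesis gene, the only one of 17 NRF2 targets (1.11 ± 0.12). Of 22 p53 targets 2 fell, among them Gadd45a (-0.80 ± 0.15), or 3 adjusted over the list alone. Of 21 ATF4 targets Atf3 rose (0.59 ± 0.15, adjusted p = 0.0482, and 0.0757 with median centring) and 2 fell, namely Chac1, a glutathione-degrading enzyme gene (-1.19 ± 0.17), and the amino acid transporter gene Slc3a2 (-0.37 ± 0.10; adjusted p = 0.111 with the block and 0.0573 without the 2 deviating arrays). Among 23 S phase genes Ccne2, which encodes a cyclin E, rose by 1.68 ± 0.20, and among 25 mitosis genes Aurka and Cdc20, which encode a spindle kinase and an activator of the anaphase-promoting complex, fell by 0.77 ± 0.15 and 0.63 ± 0.13. Adjusted over the list alone, 5 mitosis genes fell and 1 S phase gene fell. Of 9 senescence genes 2 rose, the cell-cycle inhibitor genes Cdkn1b (1.26 ± 0.09) and Cdkn1c (0.95 ± 0.22), and of 19 genes of cholesterol and fatty acid synthesis Stard4 and Sqle rose by 0.62 ± 0.16 and 0.35 ± 0.08, calls that were lost with the block (adjusted p = 0.0532 and 0.0781). That lipid list had a median of -0.19 (camera adjusted p = 0.162), and adjusted over the list alone 2 members rose and 3 fell. None of 16 acetyltransferase, 17 unfolded-protein-response, 24 interferon-stimulated, 23 collagen and matrix or 14 smooth-muscle genes passed, also adjusted over the list alone. Krt19, Sox9 and Fabp4, on the lists of epithelium, cartilage and adipocyte markers, rose by 2.01 ± 0.17, 1.01 ± 0.21 and 1.20 ± 0.20. No marker of macrophages, endothelium, skeletal muscle, neural cells or erythroid cells passed. Leaving out 1 array at a time ended the calls of Stard4, Sqle, Slc3a2 and Atf3 in 5 of 6 cases, of Sox9 and Cdkn1c in 3 and of Slc40a1 and Cdc20 in 2, the DP array of line 4 being among them for each but Cdkn1c, which was lost without the ethanol array of line 3 or 4 or the DP array of line 5.

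**Figure D1:**
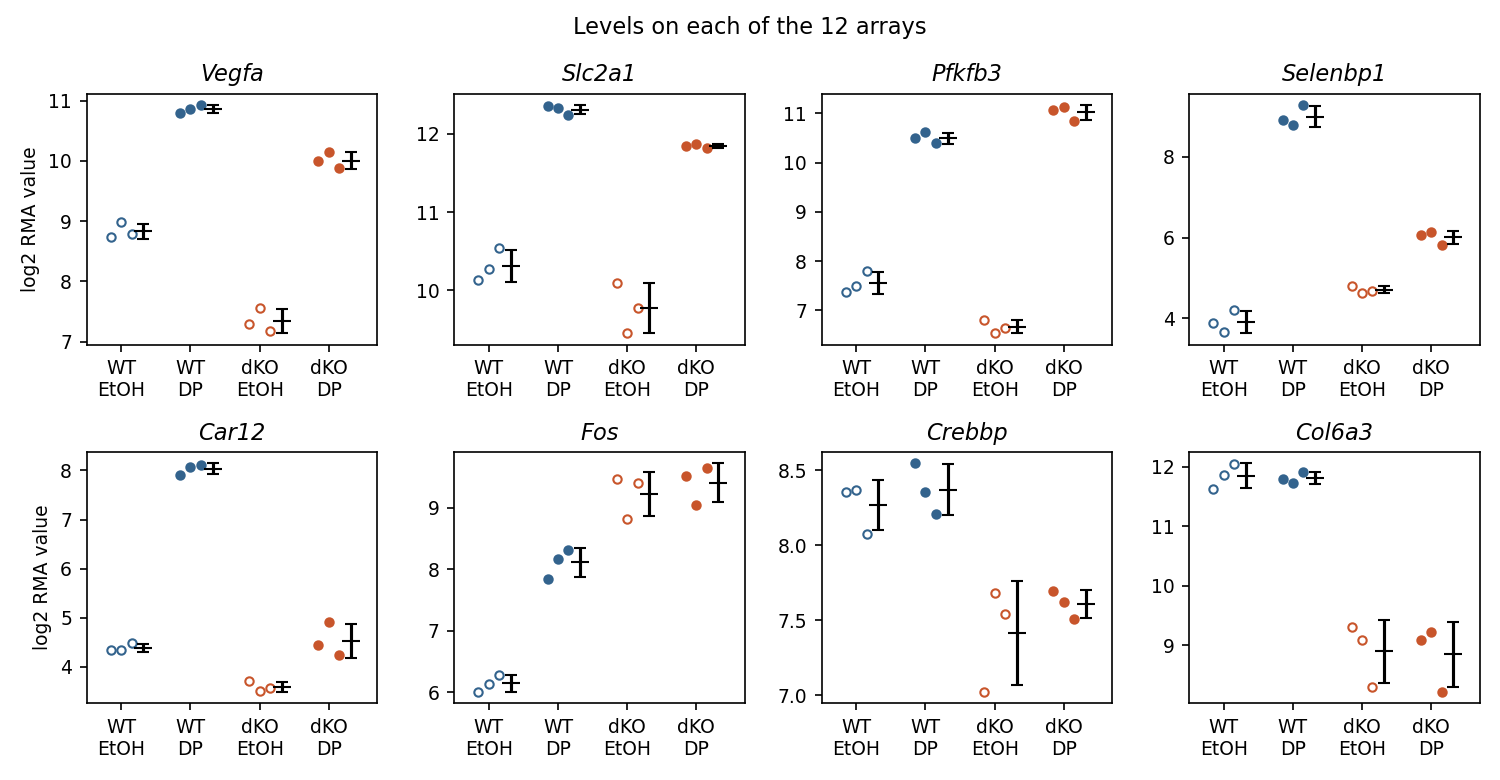
Log2 RMA values of 8 genes on each array, with ethanol arrays as open and DP arrays as filled circles, wild type in blue and dKO in orange; the bar beside each group gives its mean and SD over 3 arrays, and panels differ in range. Vegfa and Slc2a1 rose with DP in both genotypes, Pfkfb3 rose by 4.36 in dKO against 2.95 in wild type, and Car12 and Selenbp1 reached lower values under DP in dKO.

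The second comparison asked the same question in dKO cells. Pfkfb3 rose by 4.36 ± 0.13 (adjusted p = 7.48e-10), Ankrd37 by 4.20 ± 0.11 and Ak4, an adenylate kinase gene of mitochondria, by 3.64 ± 0.11. Stc1 and Stc2, which encode the secreted stanniocalcins, rose by 3.32 ± 0.18 and 3.01 ± 0.10, and Ndrg1 by 3.11 ± 0.14. Vegfa rose by 2.67 ± 0.12, Slc2a1 by 2.07 ± 0.15, Bnip3 by 2.61 ± 0.11 and Egln3 by 2.82 ± 0.13. Falls included those of the chemokine gene Ccl7 (-1.66 ± 0.19), Txnip, encoding a thioredoxin inhibitor that limits glucose uptake (-1.37 ± 0.10), and Mid1ip1 (-1.15 ± 0.13). In all, 256 genes changed, of which 172 rose and 84 fell. The count was 153 without the dKO DP array of line 1 and 160 without that of line 6, and 67.2% of the called genes rose, against 77.6% after cyclic loess and 40.8% of 1477 genes with array weights.

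Both HIF lists rose in dKO cells. Of the 20 genes of glycolysis and glucose uptake 17 rose and none fell, or 19 adjusted over the list alone, with a median of 1.00 (camera adjusted p = 9.68e-49, and 0.00546 with an estimated correlation). Hk2 rose by 2.52 ± 0.09, the monocarboxylate transporter gene Slc16a3 by 2.08 ± 0.13, Ldha by 0.82 ± 0.09 and Pgk1 by 0.78 ± 0.10. Of the 41 other HIF targets 30 rose and none fell, or 35 adjusted over the list alone, with a median of 1.30 (camera adjusted p = 3.44e-79, and 2.21e-05 with an estimated correlation). Adm rose by 1.25 ± 0.12, while Car9 changed by 0.18 ± 0.22 and did not pass. Vhl rose by 0.71 ± 0.11 as the only called HIF pathway component; Hif1a, Epas1 and Arnt changed by -0.10 ± 0.17, 0.10 ± 0.17 and -0.09 ± 0.09. Adjusted over the list alone, 1 other component fell.

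Of the 26 immediate early genes 3 rose in dKO, or 5 with 5 falls adjusted over the list alone. They were Ier3 (1.47 ± 0.10), Fosl1 (0.99 ± 0.19) and the prostaglandin synthase gene Ptgs2 (0.72 ± 0.13). No CREB target passed, against 5 rises adjusted over the list alone, 3 without the 2 deviating arrays and 1 with the MEF line as a block; the list's median was 0.14 and its camera call (adjusted p = 0.0109) was lost with an estimated correlation (adjusted p = 0.213 with an estimated correlation) and without the dKO ethanol array of line 5 (median 0.06) or the DP array of line 1 (median 0.12). Among inflammatory genes Tnfaip3 and Lif rose by 1.81 ± 0.10 and 0.62 ± 0.10, and Ccl7 and Ccl2 fell by 1.66 ± 0.19 and 0.83 ± 0.17. Tfrc rose by 1.51 ± 0.28, Ccne2 by 1.51 ± 0.20, Krt19 by 1.43 ± 0.17 and Fabp4 by 1.06 ± 0.20. Among mitosis genes Aurka, Cdc20 and the kinase gene Plk1 fell by 0.84 ± 0.15, 0.69 ± 0.13 and 0.90 ± 0.20, against 10 falls and 1 rise adjusted over the list alone. Leaving out 1 array at a time ended the calls of Tfrc, Ptgs2, Ccl2, Cdc20 and Fabp4 in 4 of 6 cases and of Fosl1 and Aurka in 2, the DP array of line 5 being among them for each, and of Plk1 in 5. Plk1 did not pass without the 2 deviating arrays (adjusted p = 0.112), and Tfrc, Ptgs2 and Lif did not with the mean of probe sets (adjusted p = 0.051, 0.189 and 0.147). In a fit of only the dKO arrays Fosl1, Ccl2, Plk1, Aurka and Cdc20 did not pass (adjusted p = 0.122, 0.061, 0.181, 0.0855 and 0.0839). In the other lists no member passed over all genes, while adjusted over the list alone 1 p53 target and 1 adipocyte marker fell and 1 interferon-stimulated gene rose. The beta-actin difference was higher on all 3 DP arrays than on the ethanol arrays within each genotype, and both deviating arrays were ethanol arrays, beside each gene group of the DP comparisons. The GAPDH difference did not rise in this way, as it overlapped between treatments in wild type and was not higher with DP in dKO. With the beta-actin difference as a covariate the DP counts were 350 genes in wild type and 86 in dKO, and the covariate itself was called for 0 genes. The covariate multiplied the changes of the called genes by medians of 1.01 and 0.987, and all kept their sign. It multiplied the standard errors by medians of 1.47 and 1.52, so the lower counts came with wider errors rather than smaller changes. Without the 2 deviating arrays the counts were 1061 genes in wild type and 284 in dKO.

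**Figure D2:**
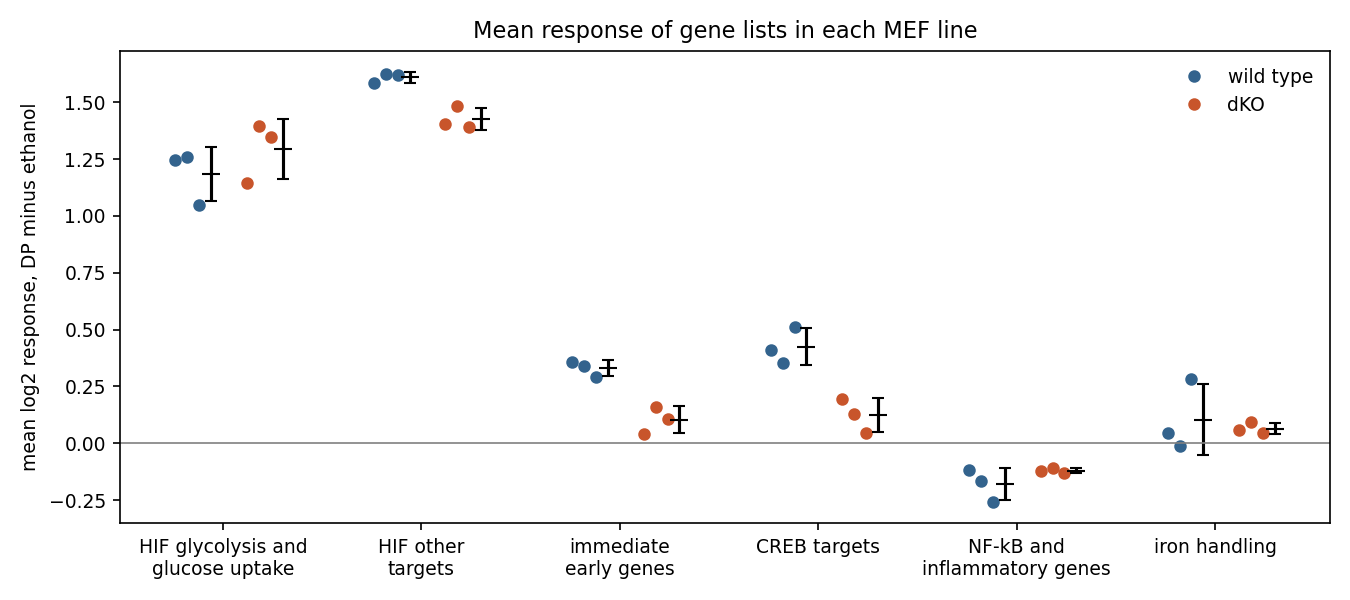
Mean log2 response (DP minus ethanol) of 6 gene lists in each of the 3 wild-type (blue) and 3 dKO (orange) MEF lines; the bar beside the points gives the mean and SD over 3 lines. Responses of glycolysis genes overlapped between genotypes, and those of CREB targets were 0.43 in wild type and 0.12 in dKO.

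The third comparison, between the DP responses themselves, asked which responses differ between dKO and wild-type cells. Selenbp2 and Selenbp1 responded less in dKO, by -3.91 ± 0.25 and -3.80 ± 0.22 (adjusted p = 1.42e-05 and 1.01e-05). Car12 followed with -2.71 ± 0.21, Slc2a3 with -2.09 ± 0.28, the small GTPase gene Rab33a with -2.16 ± 0.24 and Cdk5r1, which encodes an activator of the kinase CDK5, with -2.03 ± 0.15. Cacna1h, a calcium channel gene, and Amz1 differed by -2.27 ± 0.27 and -2.25 ± 0.19, with 2 and 3 of their 4 group means near the blank controls. Responses larger in dKO were those of Ak4 (1.65 ± 0.15), Pfkfb3 (1.41 ± 0.18), Prelid2 (1.16 ± 0.15), Bnip3 (1.08 ± 0.16), Tnfsf9, a TNF-family ligand gene (1.00 ± 0.18), Slc16a3 (0.96 ± 0.18) and Fam162a (0.63 ± 0.12). The larger response of Bnip3 went with a lower ethanol mean in dKO, as its genotype difference under DP did not pass. Pfkfb3 lay between 6.55 and 6.81 log2 on dKO and between 7.36 and 7.80 on wild-type ethanol arrays. Under DP it lay between 10.9 and 11.1 on dKO and between 10.4 and 10.6 on wild-type arrays. Ahr, which fell in wild type and changed little in dKO, differed by 1.70 ± 0.30 and did not pass without the 2 deviating arrays (adjusted p = 0.0806). The test called 96 genes, 88 with a lower and 8 with a higher value in dKO. Without the 2 deviating arrays it called 111. With the MEF line as a block Tnfsf9 and Fam162a did not pass (adjusted p = 0.0839 and 0.155), and with the mean of probe sets Ahr, Prelid2 and Fam162a did not (adjusted p = 0.0733, 0.0556 and 0.479). Leaving out 1 of the 12 arrays at a time ended the calls of Ahr in 6 cases, Tnfsf9 in 8, Slc16a3 in 9 and Fam162a in 10, the dKO DP array of line 5 being among them for each.

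Of the 522 genes that rose in wild type, 86 responded less in dKO, 7 responded more and 463 had the same sign in dKO; both tests use the wild-type arrays, unlike the held-out share below. Both genotypes called 150 rising and 46 falling genes in common, against 5.25 and 1.41 for independent lists of these sizes. The DP responses share no arrays, but both tests use the same estimate of spread for a gene, so the calls are not fully independent. Genes chosen as rising at least 2-fold from 2 wild-type lines kept 56.4% ± 0.727 (SD over 3 choices of the held-out line) of the held-out wild-type response in dKO. For falling genes, of which 10 to 22 were chosen, this share was 44.9% ± 9.89. All 3 choices used the same dKO lines, so these SDs hold no spread between dKO lines. Without 1 dKO line the share of rising genes was 55.0% to 58.1%.

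HIF target lists, which were fixed beforehand, kept larger shares. The genes behind the shares above were chosen by their change in wild type, which favours genes that respond more there. Shares of genes chosen in dKO were not computed. The mean response of glycolysis genes was 1.18 ± 0.12 in wild type and 1.29 ± 0.13 in dKO lines (SD, n = 3 lines; exact permutation p = 0.4). Other HIF targets responded by 1.61 ± 0.02 and 1.43 ± 0.05 (SD, n = 3), which is 88.7% of the wild-type mean (exact permutation p = 0.1, the smallest that 3 against 3 lines can give). Within the glycolysis list Pfkfb3 and Slc16a3 responded more and Slc2a3 and Gbe1 (-1.42 ± 0.18) less, while 9 and 2 passed adjusted over the list alone. Its median difference was 0.21, with a camera adjusted p of 0.0014 that was lost with an estimated correlation (adjusted p = 0.714 with an estimated correlation) and without the wild-type ethanol array of line 5 (median 0.18). Among other HIF targets 3 responded more, including Ak4 and Bnip3, and 2 less, against 10 and 11 adjusted over the list alone (median -0.13, camera adjusted p = 0.761). Vegfa, Slc2a1, Egln3, Adm and Ankrd37 differed by 0.64 ± 0.17, 0.07 ± 0.21, -0.60 ± 0.18, -0.75 ± 0.17 and -0.65 ± 0.16, none of which passed in the fit without array weights. With array weights, whose fit stopped before convergence, Vegfa and Adm passed (adjusted p = 0.015 and 0.0203). Ldha (0.58 ± 0.12, adjusted p = 0.0659) and Car9 (-0.96 ± 0.31, adjusted p = 0.459) did not pass in that fit, but did without the 2 deviating arrays (adjusted p = 0.0376 and 0.00543) and with array weights (adjusted p = 0.0068 and 0.00531). Ldha also passed with an intensity trend, cyclic loess, the dimmest 40% of genes left out and the mean of probe sets (adjusted p = 0.00429, 0.0477, 0.0458 and 0.0394).

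Of the CREB targets Fos, Sik1 and Nr4a3 responded less in dKO (-1.80 ± 0.28, -1.33 ± 0.19 and -1.14 ± 0.15), or 4 less and 1 more adjusted over the list alone. Fos and Nr4a3 were already at 9.23 and 8.29 log2 in dKO ethanol arrays, above the 8.11 and 7.36 reached in wild type under DP. The CREB list had a median of -0.12 (camera adjusted p = 0.0596, and 0.0428 with the MEF line as a block). With that block the p53, interferon, S phase and senescence lists were called too, each at an adjusted p of 0.0428, with medians of 0.10, 0.10, -0.16 and -0.15. Without the block these 4 lists had camera adjusted p = 0.066, 0.0596, 0.103 and 0.0669, and after cyclic loess CREB, p53 and interferon were called (adjusted p = 0.0448, 0.0443 and 0.0386). In the order CREB, p53, interferon, S phase and senescence, adjusted p = 0.534, 0.534, 0.714, 0.858 and 0.534 with an estimated correlation. Fos and Nr4a3 were also the only called immediate early genes, against 7 lower and 1 higher adjusted over the list alone. Further single members with smaller responses in dKO were Lif (-1.29 ± 0.14), Mt1 (-1.31 ± 0.14), Vhl (-1.07 ± 0.16), Gclc (-0.98 ± 0.18) and Cdkn1b (-0.94 ± 0.13). With the mean of probe sets Nr4a3 and Lif did not pass (adjusted p = 0.0817 and 0.0739), and Gclc did not in 6 of 12 fits without 1 array, the dKO DP array of line 5 among them. Xist, the Y-linked genes and the beta-actin difference separated the genotypes beside each of these groups.

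**Figure D3:**
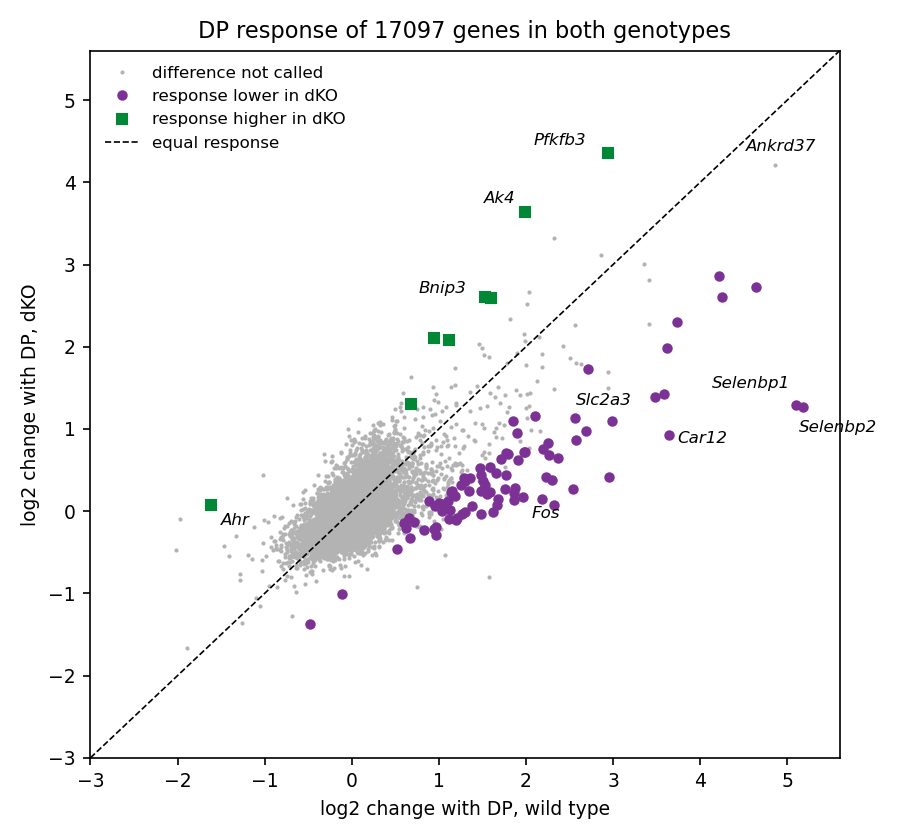
Log2 change with DP in wild type (horizontal) and dKO (vertical) for each gene, with the 88 genes whose response was called lower in dKO as purple circles and the 8 called higher as green squares. Points on the dashed line have equal responses; Selenbp1, Selenbp2, Car12 and Slc2a3 lie below it, and Pfkfb3, Ak4 and Bnip3 above.

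The fourth comparison asked how dKO cells differ from wild type in ethanol. Genes of the extracellular matrix were lower in dKO. Of 23 collagen and matrix genes 22 were lower, or 23 adjusted over the list alone, with a median of -1.68 (camera adjusted p = 4.34e-17, and 0.0967 with an estimated correlation). The proteoglycan genes Dcn and Lum differed by -3.73 ± 0.29 and -3.53 ± 0.33, the collagen gene Col6a3 by -2.95 ± 0.27 and the metalloproteinase inhibitor gene Timp3 by -2.75 ± 0.12. Col18a1 and Col5a3 (both -4.07, SE 0.15 and 0.18), the matrix gene Dpt (-4.34 ± 0.25) and the collagenase gene Mmp13 (-5.07 ± 0.19, at the blank level in dKO) were among the largest decreases. All 14 smooth-muscle contractile and SRF target genes were lower, also adjusted over the list alone, with a median of -1.15 (camera adjusted p = 5.51e-09, and 0.154 with an estimated correlation). Among these, the myosin gene Myh11 differed by -2.09 ± 0.26 and the calponin gene Cnn1 by -2.0 ± 0.19. In all, 5740 genes (33.6%) differed, 3333 higher and 2407 lower in dKO, and of 1578 with at least a 2-fold difference 696 were higher and 882 lower. Of the called genes 58.1% were higher, against 45.9% after cyclic loess.

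Lipid synthesis, amino acid and inflammatory genes were also lower in dKO. Of 19 genes of cholesterol and fatty acid synthesis 18 were lower, or 19 adjusted over the list alone, with a median of -1.25 (camera adjusted p = 2.84e-13, and 0.022 with an estimated correlation). They included the sterol demethylase gene Cyp51 (-2.0 ± 0.18), the desaturase gene Scd1 (-1.83 ± 0.10) and the sterol sensor partner gene Insig1 (-1.73 ± 0.12). Of 21 ATF4 targets 17 were lower and 3 higher, also adjusted over the list alone (median -0.79, camera adjusted p = 6.94e-07, and 0.174 with an estimated correlation). Trib3, Aldh18a1 and the amino acid transporter gene Slc7a5 differed by -1.81 ± 0.17, -1.48 ± 0.14 and -1.33 ± 0.12, while Atf3, a stress-induced transcription factor gene, was higher by 4.36 ± 0.15. Of 22 NF-kB and inflammatory genes 13 were lower and 3 higher, or 14 and 3 adjusted over the list alone (median -1.16, camera adjusted p = 2.2e-06, and 0.022 with an estimated correlation). With an estimated correlation and without the 2 deviating arrays, camera did not call this list (adjusted p = 0.0527). The chemokine genes Ccl2 and Cxcl5 differed by -3.83 ± 0.17 and -3.79 ± 0.33, and the stromelysin gene Mmp3, near the blank level in dKO, by -4.31 ± 0.27. Beside these groups the dKO cells had the beta-actin, Xist and Y-linked values given above.

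HIF targets started from lower levels in dKO. Of 20 glycolysis genes 15 were lower and 1 higher, also adjusted over the list alone (median -0.54, camera adjusted p = 3.97e-05, and 0.239 with an estimated correlation). Of 41 other HIF targets 24 were lower and 7 higher, or 25 and 9 adjusted over the list alone (median -0.68, camera adjusted p = 2.45e-05, and 0.0967 with an estimated correlation). Stc1, Ndrg1, Egln3 and Vegfa differed by -2.81 ± 0.18, -2.63 ± 0.14, -1.66 ± 0.13 and -1.49 ± 0.12, while Gbe1 was higher by 1.24 ± 0.13. Epas1, which encodes HIF-2 alpha, was higher by 1.24 ± 0.17 and Hif1a lower (-0.70 ± 0.17); in all 4 of 12 pathway components were higher and 2 lower, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.158). Of 16 acetyltransferase and coactivator genes 8 were higher and only Crebbp lower, or 9 and 1 adjusted over the list alone. Kat2b, which encodes the acetyltransferase PCAF, and Ncoa1, a nuclear receptor coactivator gene, were higher by 1.65 ± 0.15 and 1.61 ± 0.13. The list's median was 0.31 (camera adjusted p = 0.0216), a call lost with an estimated correlation (adjusted p = 0.154 with an estimated correlation) and after cyclic loess (adjusted p = 0.109, median 0.14).

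**Figure D4:**
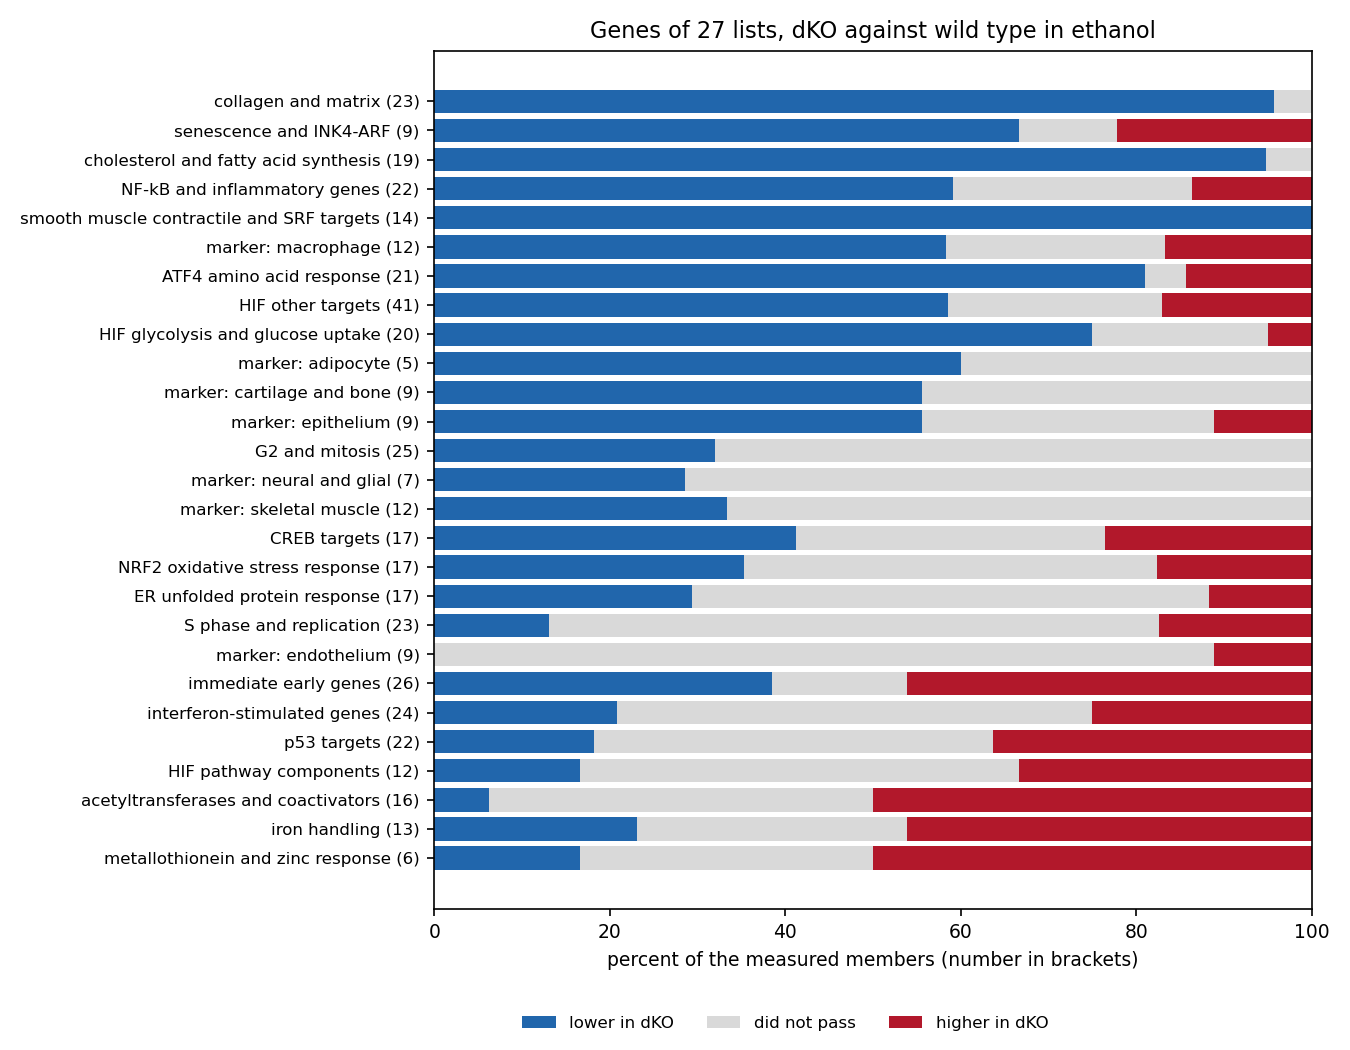
Share of the measured members of each gene list, in percent, that were lower (blue) or higher (red) in dKO than in wild type in ethanol or did not pass (grey), with the number measured in brackets and lists ordered by median difference. The 14 smooth-muscle genes were all lower, as were 22 of 23 collagen and matrix genes.

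Transcription factor genes of early responses went both ways. Of 26 immediate early genes 12 were higher and 10 lower, also adjusted over the list alone (camera adjusted p = 0.864), with Fos, Nr4a3 and Nr4a1 higher by 3.09 ± 0.20, 2.43 ± 0.11 and 1.97 ± 0.14 and Myc lower (-1.92 ± 0.13). Of 17 CREB targets 4 were higher and 7 lower, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.606); the phosphodiesterase gene Pde4b differed by -2.85 ± 0.25. Of 9 senescence genes 6 were lower and 2 higher, also adjusted over the list alone (median -1.34, camera adjusted p = 0.0184, and 0.154 with an estimated correlation). Hmga2, which encodes a chromatin protein of embryonic cells, differed by -1.75 ± 0.10, the cell-cycle inhibitor genes Cdkn1c and Cdkn2a by -1.71 ± 0.22 and -1.47 ± 0.28. Of 25 mitosis genes 8 were lower and none higher, also adjusted over the list alone (median -0.34, camera adjusted p = 0.00675, and 0.239 with an estimated correlation), led by the spindle gene Tpx2 (-0.82 ± 0.14). Of 23 S phase genes 4 were higher and 3 lower (3 and 3 adjusted over the list alone), and of 22 p53 targets 8 and 4, with Gadd45a at -1.63 ± 0.15. Iron-handling genes split into 6 higher and 3 lower of 13, zinc-response genes into 3 and 1 of 6, NRF2 targets into 3 and 6 of 17, unfolded-protein genes into 2 and 5 of 17 and interferon-stimulated genes into 6 and 5 of 24. None of these 7 last lists had a camera call, and adjusted over the list alone the counts of the last 6 were the same. Mt1 and Gsta4, a glutathione transferase gene, were higher by 1.49 ± 0.10 and 1.82 ± 0.12, and the iron exporter gene Slc40a1 and the interferon-induced Ifit3 were lower (-1.45 ± 0.18 and -2.17 ± 0.23).

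Some markers of other cell types differed between the genotypes as well, in a comparison that called 33.6% of all genes. The called shares of the neural, skeletal muscle and endothelial lists were not above that. Of 12 macrophage markers 7 were lower and 2 higher in dKO (median -0.80, camera adjusted p = 0.0797), or 3 lower and 2 higher without the 2 deviating arrays. The lysozyme gene Lyz2 lay between 6.77 and 8.88 log2 on wild-type and between 4.20 and 5.13 on dKO ethanol arrays, while the lysosomal gene Cd68 was higher in dKO by 1.53 ± 0.29. Of 7 neural markers 2 were lower (camera adjusted p = 0.0394, and 0.233 with an estimated correlation), namely the microtubule genes Stmn2 (-3.86 ± 0.17) and Tubb3 (-3.51 ± 0.30). Of 9 cartilage and bone markers 5 were lower (camera adjusted p = 0.00683, and 0.158 with an estimated correlation), led by Sox9 (-2.09 ± 0.21), and of 12 skeletal muscle markers 4 (camera adjusted p = 0.033, and 0.154 with an estimated correlation), led by the desmin gene Des (-1.20 ± 0.28). Adipocyte markers were lower in 3 of 5 (camera adjusted p = 0.0478, and 0.154 with an estimated correlation), among them Fabp4 (-1.84 ± 0.20), and epithelial markers in 5 of 9 with 1 higher (camera adjusted p = 0.0784), among them the keratin gene Krt18 (-2.04 ± 0.19). Without the 2 deviating arrays Des and Esam did not pass (adjusted p = 0.0519 and 0.0594). The skeletal muscle and adipocyte calls were also lost without the 2 deviating arrays (adjusted p = 0.087 and 0.106), and those 2 and the neural call after cyclic loess (adjusted p = 0.0779, 0.0727 and 0.0779). Leaving out 1 of the wild-type ethanol arrays of line 4 or 5 or the dKO array of line 1 ended 1 or more of these 3 calls. Of 9 endothelial markers only Esam was higher (0.55 ± 0.16), none passed adjusted over the list alone, and no erythroid marker passed. Counts adjusted over the list alone equalled those given for the other marker lists. The matrix, lipid and inflammatory groups above were measured in the same cultures as these markers.

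The fifth comparison set dKO against wild type under DP. It called 6057 genes, 3171 higher and 2886 lower in dKO, with 52.4% higher against 42.1% after cyclic loess. Egln3, Adm, Car9 and Ankrd37 were below wild type under DP, by -2.26 ± 0.13, -1.46 ± 0.12, -1.48 ± 0.22 and -1.34 ± 0.11, and Vegfa by -0.86 ± 0.12. Pgk1, Ldha and Bnip3 differed by 0.15 ± 0.10, 0.05 ± 0.09 and 0.04 ± 0.11 and did not pass. Hif1a was lower (-1.0 ± 0.17) and Epas1 higher (1.14 ± 0.17). Of the other HIF targets 24 were lower and 5 higher, or 26 and 7 adjusted over the list alone (median -0.50, camera adjusted p = 1.84e-06, and 0.0601 with an estimated correlation). Of the glycolysis genes 9 were lower and 1 higher, or 10 and 1 adjusted over the list alone (median -0.25, camera adjusted p = 0.0296, and 0.515 with an estimated correlation). All 23 collagen and matrix and all 14 smooth-muscle genes were lower, with medians of -1.68 and -1.22 (camera adjusted p = 4.58e-16 and 9.33e-09; 0.0895 and 0.176 with an estimated correlation). Of the 19 cholesterol and fatty acid genes 17 were lower, or 18 adjusted over the list alone (median -1.14, camera adjusted p = 8.44e-12, and 0.0316 with an estimated correlation). Among ATF4 targets 16 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 2.82e-06, and 0.224 with an estimated correlation), and among inflammatory genes 14 and 2, or 15 and 2 adjusted over the list alone (camera adjusted p = 1.74e-06, and 0.0316 with an estimated correlation). With an estimated correlation and without the 2 deviating arrays, camera did not call the inflammatory list (adjusted p = 0.0547). Mitosis genes were lower in 12 of 25 and senescence genes in 7 of 9 with 1 higher (camera adjusted p = 0.00719 and 0.000556; adjusted p = 0.26 and 0.0693 with an estimated correlation), with equal counts adjusted over the list alone. Acetyltransferase and coactivator genes were higher in 8 of 16, or 9 adjusted over the list alone, with Crebbp lower (camera adjusted p = 0.00853, and 0.0913 with an estimated correlation). Cartilage markers were lower in 6 of 9 and adipocyte markers in 4 of 5, also adjusted over the list alone (camera adjusted p = 0.00853 and 0.0239; adjusted p = 0.193 and 0.115 with an estimated correlation). The remaining lists had no camera call. Of macrophage markers 8 of 12 were lower and 2 higher, or 8 and 3 adjusted over the list alone, beside the same separation of Xist, Y-linked genes and beta-actin as in ethanol. Without the 2 deviating arrays the genotype counts were 6352 genes in ethanol and 7661 under DP.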

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

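Of the tests in this part, the ceiling and RNA integrity tests were set before their results were seen, and the tests of exposure, sex, sex chromosomes and the 2 deviating arrays were chosen after the result was seen.

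The DP responses differed between genotypes by the test of the difference itself for 96 genes. The glycolysis list (median 0.21) was called by camera (adjusted p = 0.0014), but not with an estimated correlation (adjusted p = 0.714 with an estimated correlation). In fry, which tests a list against no change rather than against the other genes, it had adjusted p = 0.344, and its mean responses per line gave an exact permutation p of 0.4. Larger values in dKO were those of Ahr (1.70), Ak4 (1.65), Pfkfb3 (1.41), Prelid2 (1.16), Bnip3 (1.08), Tnfsf9 (1.00), Slc16a3 (0.96) and Fam162a (0.63). Lower values were those of Selenbp2 (-3.91), Selenbp1 (-3.80), Car12 (-2.71), Cacna1h (-2.27), Amz1 (-2.25), Rab33a (-2.16), Slc2a3 (-2.09), Cdk5r1 (-2.03) and Fos (-1.80). Members of the fixed lists with lower values were also Gbe1 (-1.42), Sik1 (-1.33), Mt1 (-1.31), Lif (-1.29), Nr4a3 (-1.14), Vhl (-1.07), Gclc (-0.98) and Cdkn1b (-0.94).

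Of these 96 genes 88 responded less, or more negatively, in dKO. A weaker exposure to DP or a compressed signal in dKO that shrank all responses alike would also shrink the glycolysis list. That list kept at least 96.6% of its wild-type mean response in each dKO line. Genes chosen as rising at least 2-fold in wild type kept at most 57.0%, as a mean of the dKO lines. These values argue only against shrinkage that is alike for all responses, and choosing genes by their wild-type rise may lower their share. Starting levels differed as well. In ethanol the median difference between dKO and wild type was -0.54 for the glycolysis list, against 0.15 for the genes with a smaller rise in dKO. A weaker exposure that affects genes unequally, or that is offset by a lower starting level, was not tested. A ceiling from high starting levels would bring the 86 genes with a smaller rise to the wild-type DP level. Of these, 80.2% were called lower in dKO than in wild type under DP, although 36 were called higher in dKO in ethanol. Their median difference between dKO and wild type was -1.02 under DP and 0.15 in ethanol. The genes were chosen on the same arrays, which favours low dKO values under DP, so this share does not decide about a ceiling. Loss of CBP and p300 is a candidate explanation that cannot be told apart from embryo sex or another difference between the lines; 91 genes were called with X-linked and Y-linked genes left out, and no line separates sex from genotype.

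In ethanol 5740 genes differed between genotypes. Dosage of sex-linked genes alone is argued against, because 96.5% of the called genes with a known chromosome were autosomal, and 32.7% of X-linked against 33.8% of autosomal genes were called. An effect of embryo sex or line on autosomal genes may contribute and cannot be told apart from loss of CBP and p300, as sex went with genotype in all 6 lines. RNA integrity cannot be told apart either: with the beta-actin difference as a covariate 1130 genes were called, the outcome set beforehand for integrity as the cause. That covariate follows genotype, was itself called for 0 genes with limma, multiplied the standard errors by a median of 2.21 and the changes by 0.917, so the lower count does not separate the 2.

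The ethanol arrays of wild-type line 5 and dKO line 1 deviated from their groups in the same genes, although they share neither line nor genotype. A lasting property of the lines is argued against as the whole cause, since the ethanol and DP deviations of these lines correlated at most at 0.326. RNA mixed between the 2 samples would make their deviations oppose each other, and they correlated at 0.844. The highest correlation of any other pair of a wild-type and a dKO array was 0.670. These pairs include those with 1 of the 2 arrays, and arrays of a group mirror each other's deviations, so they are no independent background. Lower RNA integrity cannot be told apart from other causes: against the highest other array of the group, the beta-actin difference lay at 0.01 log2 on the wild-type and -0.0515 on the dKO array, and that of GAPDH at -0.03 and 0.0039, so the signs go both ways. Shared handling of these 2 cultures or arrays may explain the pattern and was not tested, and no biological explanation was tested.

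In control probe sets outside the comparisons, the cre minus the bio hybridization controls differed by 0.85 log2 between genotypes, with 3.74 ± 0.10 in wild-type and 4.60 ± 0.08 in dKO lines (SD, n = 3 lines; exact permutation p = 0.1, the smallest possible). All cultures received Cre adenovirus, and whether its RNA reaches the cre probe sets was not tested.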

How the results depend on the processing

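The fits without the 2 deviating ethanol arrays, at either correlation, without their lines and without sex-linked genes were chosen after the data were seen; the other alternatives were planned. No called named gene or list changed direction. The share of called genes that rose moved below 50% in 3 cases: 40.8% rose for DP in dKO with array weights, which called all 256 genes of the fit without them, and 45.9% and 42.1% were higher for genotype in ethanol and under DP after cyclic loess. Array weights, whose fit stopped before convergence, gave 1295 genes for DP in wild type, 1477 in dKO and 267 for the difference; for these and the values that follow the cause was not tested, except where fewer arrays or a stricter threshold make the count smaller. Only the arrays compared gave 142 genes for DP in dKO. A fold minimum of 1.5 left 3509 and 3684 genes for genotype in ethanol and under DP. Leaving out 1 array gave 538 to 680 genes for DP in wild type, 153 to 292 in dKO, 4724 to 6180 and 4999 to 5221 for genotype, and 69 to 109 for the difference. The lowest counts came without the wild-type DP array of line 4 (538) and without the dKO DP arrays of line 1 (153) and line 6 (160). The median difference of the glycolysis list, 0.21, was not called with an estimated correlation (0.21, and 0.24 without the 2 deviating arrays) or fry (0.21), nor without the wild-type ethanol array of line 5 (0.18), and ranged from 0.15 to 0.27 over the arrays left out. The share kept by rising genes was 53.8% with a minimum of log2(1.5), 59.0% for the 100 genes of largest change, 57.8% after cyclic loess and 55.0% to 58.1% without 1 dKO line. For falling genes it was 58.6% and 60.2% in the first 2 settings and 43.2% to 49.4% without 1 dKO line. With the MEF line as a block, 807, 267 and 89 genes were called for DP in wild type, DP in dKO and the difference, of which 704, 211 and 78 were also called without it; as a random block it gave 5720 and 6052 genes for genotype. Among named genes and lists the block changed no call other than those given above. Without the 2 deviating arrays camera also called the p53, mitosis and lipid synthesis lists downward for DP in wild type (medians -0.23, -0.13 and -0.20; adjusted p = 0.011, 0.00786 and 0.011), immediate early genes upward and mitosis genes downward in dKO (medians 0.11 and -0.20; 0.0482 and 0.00297) and p53 targets upward in the difference (0.10; 0.0203). With all arrays these lists had camera adjusted p = 0.273, 0.224, 0.162, 0.106, 0.132 and 0.066. Without the 2 arrays they had adjusted p = 0.342, 0.658, 0.318, 0.989, 0.989 and 0.739 with an estimated correlation. Without the lines of these arrays, with the block, 905, 350 and 95 genes were called, and without sex-linked genes 790, 248, 5549, 5848 and 91. Over all settings, values of named genes kept their side of the threshold in 6590 cases, lost a call in 218 and gained one in 43; lists did so in 1584, 72 and 72. An estimated correlation ended 25 list calls, and 28 without the 2 deviating arrays. Unlike camera, which sets a list against the other genes, fry tests it against no change; 2 lists called by camera were not called by fry, and 21 were called by fry alone. Levels near the blank controls, 3.28 to 3.53 log2, limit what changes of dim genes can show.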

Other observations

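The splits of the samples were planned, and the genes named for the 2 deviating arrays were chosen, and that test made, after the result was seen.

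Some genes outside the fixed lists were among the largest differences between dKO and wild-type cells in ethanol. Clu, which encodes the secreted chaperone clusterin, was higher in dKO by 4.15 ± 0.19, Sort1, which encodes the sorting receptor sortilin, by 3.60 ± 0.12, and Atp6v0e2, a proton pump subunit gene, by 3.81 ± 0.14. Chrnb1, a subunit gene of the muscle acetylcholine receptor, was higher by 3.49 ± 0.10. The surface antigen gene Ly6c1 and Pla2g7, which encodes a secreted phospholipase, were lower (-4.24 ± 0.20 and -4.22 ± 0.30).

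The ethanol arrays of wild-type line 5 and dKO line 1 were each set against the mean of the other 2 arrays of their group. They had lower values for Akap9 (-1.72 and -1.83), the checkpoint kinase gene Chek1 (-1.56 and -1.67), the replication timing gene Rif1 (-1.71 and -1.55) and Aspm, a spindle gene (-1.45 and -1.49). Values were higher for the mast cell protease gene Mcpt8 (0.78 and 1.13) and the granzyme gene Gzme (0.90 and 1.51). Macrophage markers had median deviations of 0.67 and -0.01 on these 2 arrays. The S phase list, unlike Chek1 and Rif1, was higher on both (medians 0.26 and 0.40), as was the glycolysis list (0.33 and 0.21). The mitosis list had medians of -0.09 and -0.01.

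For each count of genes, the 6 arrays or lines can be split in 10 ways into 3 and 3, too few for a share under 0.05, and only 1 split, the real one, gave as many genes. The other splits leave the treatment or genotype effect inside their groups, which widens the spread and lowers their counts. Their counts are therefore no background for the real ones. For DP in wild type the real split gave 808 genes and the highest other 0; for DP in dKO these were 256 and 5, the 5 from a split that parts fewer pairs of the same line. Genotype in ethanol gave 5740 and 0, genotype under DP 6057 and 0, and the difference, on responses per line, 89 and 0.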
